A study of Mus musculus with 12 samples.

How the data were processed

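Trigeminal ganglia, the sensory ganglia that innervate the face and the meninges, were taken from 12 CD1 mice, an outbred stock. Per the series description, 6 of the mice had responded to PACAP (pituitary adenylate cyclase-activating polypeptide) and 6 had not, with 3 males and 3 females in each group, and the libraries were sequenced with paired-end reads on an Illumina HiSeq. Per the labels' protocols, the ganglia were frozen after dissection, and an outside company extracted the RNA and made libraries with poly A selection. Each library came from its own mouse. The title of each sample gave its response group and replicate number, and the characteristics gave its sex. How a response was scored, and how long before dissection a mouse had received PACAP, is not given in the sources used here.

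The authors deposited 1 table with 1 value per Ensembl gene and mouse, and its values were taken as FPKM, the fragments per kilobase of gene model scaled to the depth of the library. The unit was not named in the header of the deposited table and was inferred from its values. The totals per mouse differed, from 286388 to 358590, and in genes with a single exon the products of value and length piled up at 1 step per mouse, as the FPKM of whole fragments would. Per the submitters' processing notes, STAR 2.6.0a and StringTie 1.3.5 were used with the GRCm38 and mm10 builds. The annotation release, the settings and any filter are not given in the sources used here. No raw counts were used, and whole fragments were not recovered: between 19.4% and 28.0% of the single-exon values lay within 0.05 of a whole step, against 10.0% by chance. The size of the step implied between 17300000 and 38700000 fragments per mouse, with a mean of 28100000 in responders and 27100000 in nonresponders, so that precision differed between mice. Interval estimates that need read counts were not made.

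The table held 51341 genes. Symbols, types and coordinates came from the GENCODE M21 annotation of GRCm38, which held 51076 of the identifiers, and the other 265 kept their identifier as name. An FPKM of 0 was listed in all mice for 15903 genes. Because single libraries listed near 0 values for widely used genes, an exact 0 was read as a listing and not as proof of absence, and genes with any 0 are given as values per library or as ranges. No 2 columns were identical (0 pairs), and 0 columns belonged to other samples.

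Expression was tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes without trend or robust options, prior degrees of freedom 2.23). Genes with at least 1 FPKM in at least 3 mice entered, which left 14203. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Responders were compared with nonresponders over all mice with sex as a covariate (9 residual degrees of freedom), within males and within females from 4 cell means over all 12 mice, and between the sexes by the interaction. Females were compared with males with the response group as a covariate. Adjusted p values are Benjamini-Hochberg values over all genes tested, 2-sided, with a threshold of 0.05. The choice of samples, tests, gene lists and alternatives was made before the data were examined. The design had allowed for a count table, and the branch written for FPKM values was used.

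A set of 46 gene lists covered PACAP and CGRP (calcitonin gene-related peptide) signalling, sensory neurons, channels, glia, other tissues near the ganglion, migraine genes and cell states. The list of PACAP, VIP and their receptors had fewer than 3 tested members, so that 45 lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The mean log2 value of a list's tested members in each mouse served as the list's score and was compared between groups with an exact permutation test over all splits of the 12 mice, 2-sided, whose smallest p is 0.00216.

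The text names genes by a fixed rule: the called genes with smallest p or largest change that are not clones, predicted models or pseudogenes, a fixed set of genes of PACAP, CGRP, the pituitary hormones and the sex chromosomes, and for each list up to 4 tested members with the smallest p. Gm6166 lies outside the rule as a predicted model and is named because only 3 genes were called. Gm2223 and Gm29650 are named likewise among 8 called genes. Fabp5, BC002163, Gm8730, Rplp0, Gm9118, Gm6477, Npm1, Actb, Casc3, Rptor, mt-Atp6, Rcan3, Itm2a and Resp18 were chosen after their values were seen. Some genes that the rule would name are not reported here. Transcripts of called genes were searched against the annotated transcripts with blastn 2.17.0 for matches of at least 90% identity over at least 200 bases (e-value 1e-20). Whether the deposited values used the strand of the reads is not given in the sources used here.

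The procedure was tested on simulated data, with 200 changed genes among 13999 in each of 10 runs, drawn from genes with a level of at least 5 FPKM. For responders against nonresponders over all mice it recovered 53.4% of genes changed 1.5-fold, 79.9% of those changed 2-fold and 95.6% of those changed 4-fold, with 5% false calls. For the comparison within males the shares were 24.9%, 60.9% and 90.9% with 6.4% false calls, and within females 25.8%, 60.7% and 89.8% with 5.8%. For the gene lists, 20 of 20 lists shifted by -0.5 on the log2 scale were called and 0 of 417 unshifted lists, at an adjusted p. The simulation drew genes independently, so it does not cover genes that vary together between mice. With 200 changed genes, a larger p passes adjustment than with the few genes called in the data. The shares of recovered genes therefore overstate recovery in the real comparisons.

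Alternatives were quantile normalization, limma with trend and robust options, array weights, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, the replicate number as a block, mice averaged by the first number of their description, each mouse left out in turn, no sex covariate, and only the mice of 1 sex for the comparisons within a sex. Fits without responder 1 and nonresponder 4, and with scores of pituitary hormone, skeletal muscle and neutrophil genes as covariates, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.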

Results

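Gene expression was measured by RNA sequencing in the trigeminal ganglia of 12 CD1 mice, 6 that had responded to PACAP and 6 that had not. PACAP is a neuropeptide of sensory and parasympathetic nerves, and the series asks whether the response, light aversion, runs in families and whether it depends on CGRP. Each group held 3 males and 3 females. Total FPKM per mouse ranged from 286388 to 358590, and between 12648 and 13994 genes reached 1 FPKM. The implied depth was lowest in responder 1, at 17300000 fragments, and highest in nonresponder 4, at 38700000. These mice also stood apart from the others: nonresponder 4 lay at 72.7 on a principal component that held 28% of the variance, and responder 1 at 69.7 on the next, with 18.7%. Genes that weighed most towards those ends included the neutrophil gene Retnlg for the first and the pituitary hormone genes Gh, Cga and Lhb for the next. Responders 3 and 4, each with 37300000 implied fragments, lay at 8.4 and -25.9 on the first. Whether depth plays a part was not tested. The description of each sample starts with a number whose meaning the labels do not give. It was 44, 45, 48 or 49 in responders and 68, 82 or 83 in nonresponders, so that every number held mice of 1 group only and cannot be told apart from the response.

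The comparison of responders with nonresponders over all mice asked which transcripts of the ganglion differ with the response. Gm6166 was the most clearly separated, at 20.6 ± 3.92 FPKM in responders and 0.948 ± 0.453 in nonresponders (SD, n = 6 per group). Ndufs5, which encodes an accessory subunit of mitochondrial complex I, stood at 43.5 ± 11.9 FPKM in responders and 16.2 ± 3.78 in nonresponders. Cthrc1, which encodes a secreted glycoprotein that limits collagen deposition, was lower in responders, at 0.937 ± 0.438 FPKM against 4.56 ± 0.725. Each of these 3 genes separated all 6 responders from all 6 nonresponders.

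By limma, 3 of 14203 genes passed an adjusted p of 0.05, 2 higher and 1 lower in responders. The log2 fold change was 3.48 for Gm6166 (SE 0.173, adjusted p = 5.39e-06), 1.37 for Ndufs5 (SE 0.168, adjusted p = 0.0225) and -1.54 for Cthrc1 (SE 0.133, adjusted p = 0.00101). At an unadjusted p under 0.05 there were 1051 genes, 459 higher and 592 lower, where chance gives 710. The groups did not overlap for 78 genes, 0.549% of those tested, against 0.216% by chance. Gm6166 (ENSMUSG00000074280) is a processed pseudogene on chromosome 9 from 57483963 to 57484371, plus strand, of GRCm38, and overlaps Gm18103 on the same strand. It matched the Fabp5 transcript at 98.3% over 409 bases, so that the split of reads between them is uncertain. Ndufs5 (ENSMUSG00000028648, chromosome 4 from 123712710 to 123718202, minus strand) matched BC002163 at 99.4% over 319 bases, and its value is uncertain for the same reason. No such match was found for Cthrc1 (ENSMUSG00000054196), a protein-coding gene on chromosome 15 from 39076932 to 39087121, plus strand.

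The Ndufs5 call was lost without responder 1 (adjusted p = 0.0673), responder 4 (0.0678), nonresponder 1 (0.0943), nonresponder 3 (0.0675) or nonresponder 6 (0.0539), within a range of 0.0166 to 0.716 over all alternatives. The count of called genes was 5 without responder 2, 6 without responder 5 and 6 without responder 6. With mice averaged by the first number of their description, which leaves 7 values in place of 12, only the Gm6166 call was left. Adjusted p was then 0.214 for both Ndufs5 and Cthrc1, with log2 fold changes of 1.39 and -1.55. Each number held mice of 1 group only, so averaging leaves fold changes about as large whether or not the number carries the difference. Neither the loss on 7 values nor the fold changes can decide that.

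**Figure D1:**
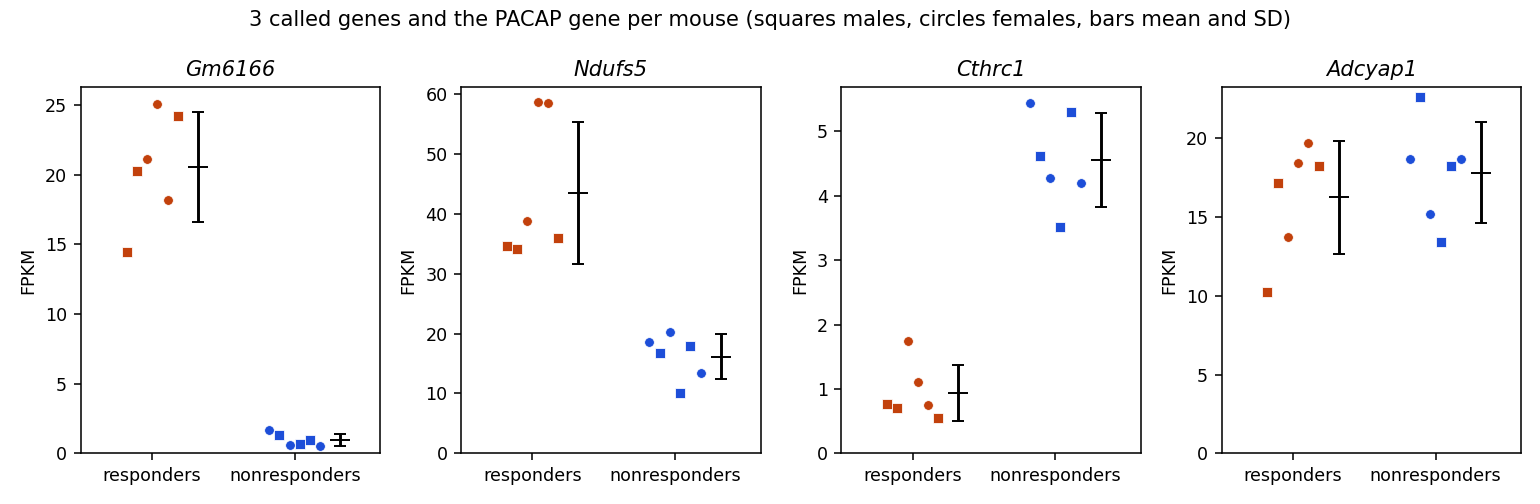
FPKM per mouse (vertical axes) of Gm6166, Ndufs5, Cthrc1 and Adcyap1 in the 6 responders and 6 nonresponders, with squares for males, circles for females and bars for mean and SD. Gm6166 lay between 14.4 and 25.1 in responders and between 0.52 and 1.64 in nonresponders, while Adcyap1 overlapped between the groups.

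The genes of PACAP and CGRP signalling showed no difference past the test. Adcyap1, which encodes PACAP, stood at 16.3 ± 3.59 FPKM in responders and 17.8 ± 3.20 in nonresponders (SD, n = 6 per group; log2 fold change -0.14, limma adjusted p = 0.859). The PACAP receptor gene Adcyap1r1 was low, at 0.678 ± 0.314 and 0.703 ± 0.182 FPKM, and was left out of the test by the filter on low values. The same held for the VPAC receptor genes Vipr2, at 0.642 ± 0.283 and 0.545 ± 0.155, and Vipr1, which ranged from 0 to 0.19 in responders and from 0.02 to 0.53 in nonresponders. Calca, the main CGRP gene of sensory neurons, stood at 36.4 ± 4.94 and 39.8 ± 11.7 FPKM (log2 fold change -0.09, adjusted p = 0.917), and Calcb, which encodes the other CGRP, at 2.13 ± 0.763 and 1.95 ± 0.437. The CGRP receptor subunit genes Calcrl (2.17 ± 0.850 and 2.84 ± 0.978) and Ramp1 (2.33 ± 1.72 and 4.41 ± 2.65) did not pass either, with adjusted p of 0.772 and 0.698. Of the 8 tested members of the CGRP list, 0 passed limma over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. The list was not called by camera (adjusted p = 0.645, and adjusted p = 0.777 with an estimated correlation). For genes of at least 5 FPKM, such as Adcyap1 and Calca, a change of 2-fold was found in 79.9% of simulated genes and one of 1.5-fold in 53.4%. These shares do not cover Calcb, Calcrl and Ramp1, which lay below that level. They were also reached with 200 changed genes per run. With only 3 genes called in the data, a gene needed a smaller p to pass. The shares thus overstate what this comparison would find.

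Genes of myelin, connective tissue and matrix had mostly lower values in responders. Of 14 myelinating Schwann cell genes, 13 had lower values in responders, with a median log2 fold change of -0.42. Pmp2, a myelin lipid-binding protein, stood at 3.25 ± 1.25 FPKM in responders and 10.4 ± 4.09 in nonresponders (SD, n = 6 per group). Gldn, a Schwann cell protein of the node of Ranvier, had 9.49 ± 2.78 and 16.2 ± 2.47, and Fa2h, which makes hydroxylated myelin lipids, 36.5 ± 7.78 and 53.8 ± 9.09. Of 34 extracellular matrix genes, 31 had lower values (median -0.44), among them Postn, at 4.42 ± 2.14 and 28.2 ± 26.3, and the collagen genes Col5a2, at 7.37 ± 1.53 and 13.5 ± 4.21, Col12a1, at 0.673 ± 0.299 and 2.25 ± 1.14, and Col16a1, at 9.40 ± 2.08 and 14.7 ± 3.02. Of 17 fibroblast and meningeal genes, 15 had lower values (median -0.69), such as Ptgds, a prostaglandin D synthase of the meninges, at 218 ± 103 and 636 ± 381, Col1a2, at 76.0 ± 16.1 and 177 ± 87.2, Slc22a6, at 0.900 ± 0.425 and 2.84 ± 1.89, and Igf2, at 7.92 ± 4.12 and 15.7 ± 9.03.

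Over all genes, 0 members of these 3 lists passed limma, while 7 Schwann cell, 17 matrix and 9 fibroblast genes had an unadjusted p under 0.05 in the lower direction. When adjusted over the list alone, 7 Schwann cell, 6 matrix and 8 fibroblast genes passed, all lower. Pmp2 shares 1226 bases at 100% with Gm37389, which makes its value uncertain. Camera called the matrix list (adjusted p = 9.41e-13), the Schwann cell list (2.25e-08) and the fibroblast list (9.46e-08) as lower, and each had an adjusted p = 0.475 with an estimated correlation. The list scores differed by exact permutation with p = 0.0216, 0.0281 and 0.013, each 0.211 after adjustment. All 3 calls held under each of the 23 alternatives run for them, with a fibroblast median of -0.46 without nonresponder 3.

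**Figure D2:**
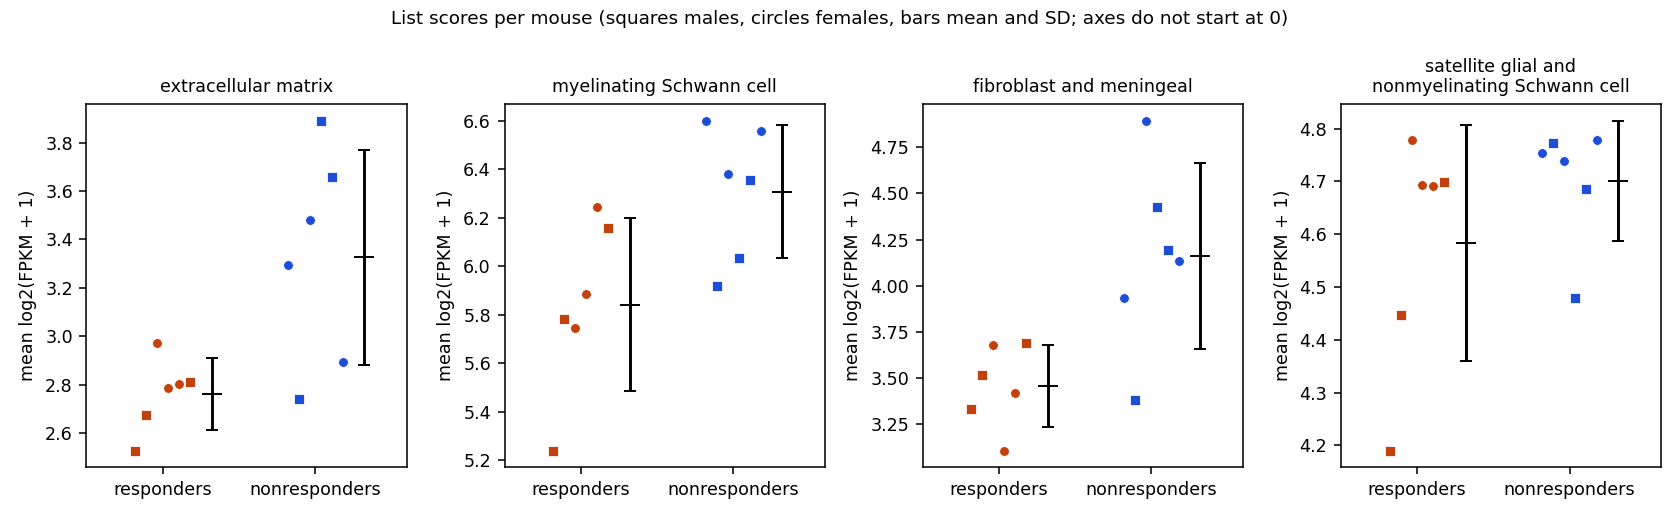
Mean log2(FPKM + 1) over the tested members of 4 gene lists per mouse, with squares for males, circles for females and bars for mean and SD, on axes that do not start at 0. The matrix score was 2.76 ± 0.149 in responders and 3.33 ± 0.443 in nonresponders, and the satellite glial score 4.58 ± 0.223 and 4.70 ± 0.114.

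The satellite glial and nonmyelinating Schwann cell list, with 11 of 17 members lower, was not called (median -0.11, camera adjusted p = 0.07, and adjusted p = 0.545 with an estimated correlation). In it, 3 genes passed when adjusted over the list alone, all lower, among them the glutamate transporter Slc1a3, at 4.13 ± 0.519 FPKM in responders and 6.61 ± 1.92 in nonresponders (n = 6 per group). This list was called without nonresponder 4 (adjusted p = 0.0253) and without responder 6 (0.0141), within 0.0141 to 0.944 over all alternatives. The mean Schwann cell score minus the satellite glial score was 1.26 ± 0.230 in responders and 1.61 ± 0.247 in nonresponders (exact permutation p = 0.0368, 2-sided). The Schwann cell score minus the endothelial and minus the macrophage score had an exact permutation p of 0.355 and 0.407, and all 3 tests were chosen after the result was seen.

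Pituitary transcripts were listed in libraries of both groups and were higher in several responders. Gh, the growth hormone gene, was listed at 63429, 5578, 1363, 78.3, 386 and 358 FPKM in responders 1 to 6 and between 18.1 and 701 in nonresponders. Prl, the prolactin gene, ranged from 56.2 to 9397 in responders and from 4.67 to 870 in nonresponders, and Cga, the common subunit of the glycoprotein hormones, from 3.49 to 2194 and from 0.43 to 19.4. Pomc ranged from 2.49 to 1878 and from 2.26 to 93.9, Lhb from 0.68 to 496 and from 0.11 to 3.24, Tshb from 0.63 to 184 and from 0.33 to 1.95, and Fshb from 0.09 to 302 and from 0 to 1.78. Pituitary cell genes other than hormones ran alongside: Dlk1 ranged from 0.45 to 243 in responders and from 0.12 to 2.22 in nonresponders, the transcription factor gene Lhx3 from 0.17 to 21.0 and from 0.02 to 0.38, Pou1f1 from 0 to 31.5 and from 0 to 0.4, and the gonadotropin-releasing hormone receptor gene Gnrhr from 0.04 to 23.97 and from 0 to 0.11. Responder 1 held the highest value of each of these genes.

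None of the 7 hormones passed limma over all genes (0, with 6 at an unadjusted p under 0.05), and 6 passed when adjusted over the list alone, all higher in responders. The smallest adjusted p over all genes among them was 0.586, for Cga (log2 fold change 3.74). Camera called the hormones (median 2.94, adjusted p = 3.46e-06, and adjusted p = 0.475 with an estimated correlation) and the 12 pituitary cell genes (median 1.3, adjusted p = 2.46e-06, and adjusted p = 0.475 with an estimated correlation) as higher. Exact permutation of the scores gave p = 0.026 for the hormones and 0.0173 for the cell genes (2-sided). Both calls held without responder 1, with a median of 2.06 for the hormones and 0.38 for the cell genes.

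**Figure D3:**
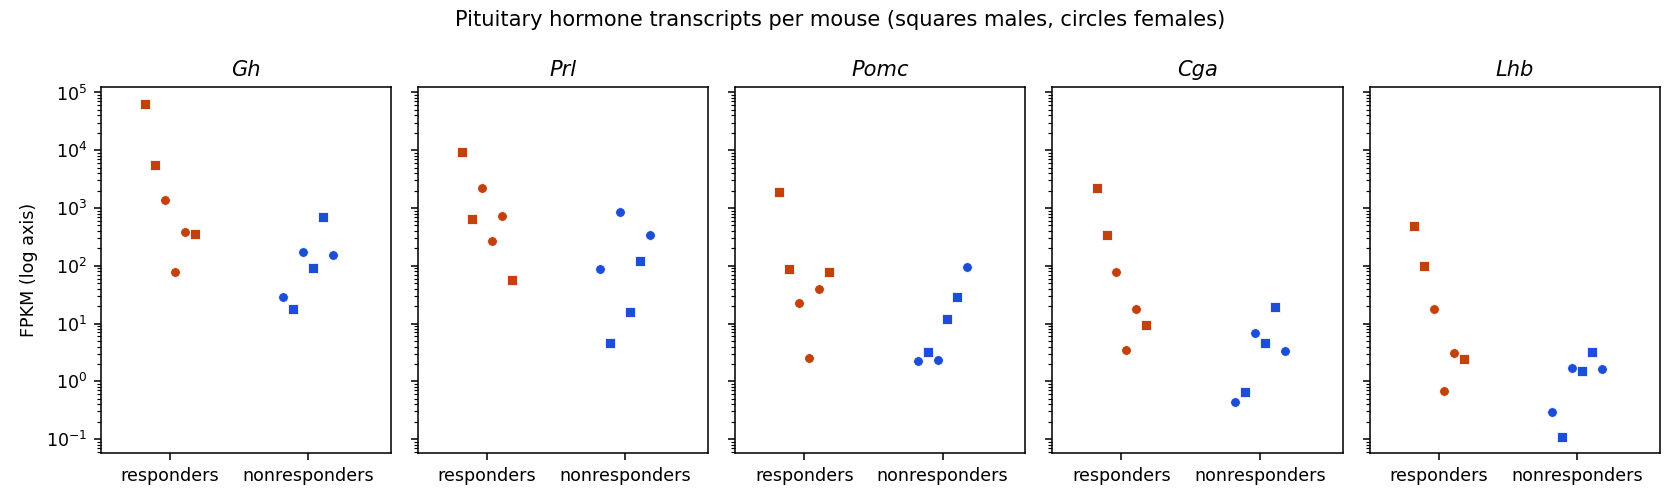
FPKM per mouse on a log axis of Gh, Prl, Pomc, Cga and Lhb in the 6 responders and 6 nonresponders, with squares for males and circles for females. Gh spanned 78.3 to 63429 in responders and 18.1 to 701 in nonresponders.

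Genes of fat, bone, skeletal muscle, neutrophils and brain had lower values in responders in lists that camera called at its preset correlation only. The 3 tested adipocyte genes were all lower (median -1.36): Adipoq, the adiponectin gene, ranged from 0 to 0.72 FPKM in responders and from 0.23 to 5.02 in nonresponders, Cfd from 0 to 0.14 and from 0 to 6.75, and Fabp4 stood at 3.09 ± 1.96 and 18.5 ± 16.3 (SD, n = 6 per group). All 6 bone and cartilage genes were lower (median -0.90), among them the osteocalcin gene Bglap2, at 2.89 ± 4.10 and 23.7 ± 18.4, and Sp7, an osteoblast transcription factor gene, at 0.607 ± 0.219 and 1.81 ± 0.855. All 13 skeletal muscle genes were lower (median -1.45), such as Myh1, at 1.53 ± 1.41 and 7.32 ± 7.23, and Mb, the myoglobin gene, at 17.6 ± 26.0 and 66.6 ± 74.5. All 14 neutrophil genes were lower (median -1.32), with Retnlg at 257 FPKM and Mmp9 at 71.0 in nonresponder 4, against at most 40.1 and 14.0 in the other mice. Among 10 central nervous system genes, all lower (median -0.49), were Gfap, the astrocyte filament gene, at 58.9 ± 15.8 and 110 ± 49.8, Mobp, an oligodendrocyte myelin gene, at 52.8 ± 32.6 and 116 ± 67.7, and Tmem119, at 1.65 ± 0.718 and 3.81 ± 1.51.

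None of these members passed limma over all genes (0), and 3 adipocyte, 2 bone and 1 central nervous system genes passed when adjusted over the list alone, with 3, 3 and 2 at an unadjusted p under 0.05, beside 1 muscle and 0 neutrophil genes. Camera called the adipocyte (adjusted p = 8.26e-05), bone (4.5e-05) and central nervous system (0.00249) lists as lower, each with an adjusted p = 0.475 with an estimated correlation. It also called the muscle (0.000893, and adjusted p = 0.545 with an estimated correlation) and neutrophil lists (0.00104, and adjusted p = 0.551 with an estimated correlation). The neutrophil call was lost without nonresponder 4 (median -0.64, adjusted p = 0.104, within 9.41e-07 to 0.806 over all alternatives). The median of muscle genes was -0.89 without nonresponder 3 and -0.91 without nonresponder 4, and that of central nervous system genes -0.74 without responder 3, -0.25 without responder 4 and -0.28 without nonresponder 6. The muscle call was lost with array weights (median -0.78, adjusted p = 0.16, within 8.16e-11 to 0.475 over all alternatives) and the central nervous system call with no filter on low values (median -0.09, adjusted p = 0.0511, within 9.51e-06 to 0.0511). Exact permutation of the scores gave p = 0.00866 for fat, 0.0368 for bone, 0.203 for muscle, 0.273 for neutrophils and 0.0952 for the central nervous system.

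The 13 mitochondrially encoded genes were all lower in responders (median -0.29), such as mt-Nd4, at 902 ± 62.4 FPKM and 1132 ± 205, mt-Nd1, at 1723 ± 176 and 2165 ± 406, and mt-Nd2, at 876 ± 83.6 and 1183 ± 307 (n = 6 per group). Pericyte and smooth muscle genes had a median of -0.38, with Acta2 at 11.5 ± 4.34 and 20.2 ± 11.8 and Cnn1 at 0.494 ± 0.375 and 1.36 ± 0.879. Endothelial genes had a median of -0.19, with the von Willebrand factor gene Vwf at 4.09 ± 1.17 and 7.27 ± 4.50 and Pecam1 at 3.63 ± 1.24 and 5.73 ± 2.72. Among cytokines (median -0.22), Cxcl12 stood at 8.88 ± 4.36 and 23.6 ± 24.8, and among cholesterol synthesis genes (median -0.10) Hmgcs1 stood at 113 ± 19.7 and 161 ± 28.5. None of their members passed limma over all genes (0) or over the list alone (0), and 5 mitochondrial, 1 pericyte, 0 endothelial, 0 cytokine and 3 cholesterol genes were lower at an unadjusted p under 0.05. Camera called these 5 lists as lower. Adjusted p was 5.12e-07 for the mitochondrial list and 0.0109 for the endothelial list, each with an adjusted p = 0.475 with an estimated correlation. It was 0.00281 for pericytes and 0.0326 for cholesterol synthesis, each with an adjusted p = 0.545 with an estimated correlation, and 0.0398 for cytokines, with an adjusted p = 0.581 with an estimated correlation. The pericyte call was lost without nonresponder 3 (adjusted p = 0.0635) or nonresponder 4 (0.0655). The cholesterol call was lost without responder 1 (0.159), responder 3 (0.149), nonresponder 1 (0.0622), nonresponder 2 (0.115) or nonresponder 6 (0.118), and the cytokine call without responder 2 (0.145), 4 (0.123), 5 (0.073) or 6 (0.0758) or nonresponder 3 (0.212), 4 (0.314) or 6 (0.0574). Medians were -0.24 and -0.23 for pericytes and -0.12 and -0.11 for cytokines without nonresponder 3 and without nonresponder 4, and for cholesterol synthesis -0.06 without responder 3, nonresponder 5 or nonresponder 6 and -0.17 without nonresponder 3. Across all alternatives adjusted p reached 0.0674, 0.298 and 0.314 for these 3 lists. The mitochondrial call was lost with tissue scores as covariates (median -0.10, adjusted p = 0.144, within 9.35e-10 to 0.144 over all alternatives).

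Neuronal lists leaned the other way by smaller amounts. Among other sensory neuropeptides (median 0.13), Nts, the neurotensin gene, stood at 6.22 ± 2.69 FPKM in responders and 1.90 ± 0.716 in nonresponders (SD, n = 6 per group) and passed when adjusted over the list alone but not over all genes (limma adjusted p = 0.339). The itch-related peptide genes Nppb, at 3.55 ± 1.25 and 2.52 ± 0.675, and Sst, at 6.81 ± 3.78 and 4.46 ± 0.972, did not pass. Of 16 pan-neuronal genes, 13 had higher values (median 0.11), such as Avil, at 22.3 ± 6.85 and 14.0 ± 2.56, and Syt1, a synaptic calcium sensor, at 10.1 ± 4.81 and 6.09 ± 2.28. Of 13 voltage-gated sodium channel genes 9 were higher (median 0.19), with Scn8a at 30 ± 6.46 and 22.2 ± 3.32, and of 14 calcium channel genes 12 (median 0.10), with Cacna2d2 at 8.19 ± 1.67 and 5.95 ± 1.26 and Cacna1c at 5.12 ± 0.459 and 4.17 ± 0.692. The GABA and glycine receptor genes, all 11 higher, had a median of 0.12, with Gabrb2 at 8.17 ± 1.21 and 6.57 ± 1.25, and glutamate receptor and transporter genes one of 0.12, with Gria4 at 14.7 ± 2.97 and 11.9 ± 1.97.

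Camera called these 6 lists as higher. Adjusted p was 0.0272 for neuropeptides and 0.0349 for sodium and calcium channels, each with an adjusted p = 0.475 with an estimated correlation. It was 0.0349 for GABA and glycine receptors and 0.0398 for glutamate genes, each with an adjusted p = 0.545 with an estimated correlation, and 0.0349 for pan-neuronal genes, with an adjusted p = 0.581 with an estimated correlation. None of the members passed limma over all genes (0), and 1 neuropeptide, 1 pan-neuronal, 1 sodium channel, 2 calcium channel, 1 GABA receptor and 0 glutamate genes were higher at an unadjusted p under 0.05. In the glutamate list 1 gene was lower at that threshold. All 6 calls were lost under quantile normalization (adjusted p of 0.0502 to 0.0676), with medians of 0.105 to 0.192. They were also lost without nonresponder 3 (adjusted p of 0.0712 to 0.204) and without nonresponder 4 (0.0974 to 0.307). Adjusted p was up to 0.328, 0.276, 0.195, 0.59, 0.261 and 0.417 over all alternatives for neuropeptides, pan-neuronal genes, sodium channels, calcium channels, GABA receptors and glutamate genes. Without nonresponder 4 their medians were 0.08, 0.04, 0.13, 0.01, 0.06 and 0.04 in the same order, and without responder 1 those of neuropeptides, pan-neuronal genes and GABA receptors were 0.21, 0.22 and 0.21. Without nonresponder 2 the medians were 0.21 for neuropeptides, 0.19 for pan-neuronal and GABA receptor genes, 0.18 for calcium channels and 0.19 for glutamate genes. Sodium channels had 0.11 without responder 2 and 0.10 without responder 3, pan-neuronal genes 0.06 without responder 2, 0.05 without responder 5 and 0.07 without nonresponder 3, and calcium channels 0.065 without responder 4. GABA receptors had 0.06 without responder 5, 0.08 without nonresponder 1, 0.05 without nonresponder 3 and 0.185 without nonresponder 5, and glutamate genes 0.08 without nonresponder 3. Calls were also lost without responder 2 (all 6 lists, adjusted p of 0.0829 to 0.195), responder 3 (neuropeptides, sodium and calcium channels and glutamate genes, 0.0574 to 0.146), responder 4 (all but neuropeptides, 0.0519 to 0.075), responder 5 (pan-neuronal genes, sodium and calcium channels and GABA receptors, 0.058 to 0.128), responder 6 (all but sodium and calcium channels, 0.0792 to 0.107), nonresponder 1 (all but neuropeptides and pan-neuronal genes, 0.0581 to 0.0978) and nonresponder 6 (GABA receptors, 0.0533).

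In all, camera called 21 of 45 lists, 8 higher and 13 lower. At the same preset correlation, other sex-balanced splits of the mice called a median of 11 lists and up to 24. Under quantile normalization it called 14, 2 higher and 12 lower, and without nonresponder 3 it called 12, 2 higher and 10 lower. With an estimated correlation 0 lists were called (3 at an unadjusted p under 0.05), and by fry in its directional test 0 (7 at an unadjusted p under 0.05). By exact permutation of the scores 8 of the called lists had a p under 0.05 and 0 an adjusted p under 0.05.

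**Figure D4:**
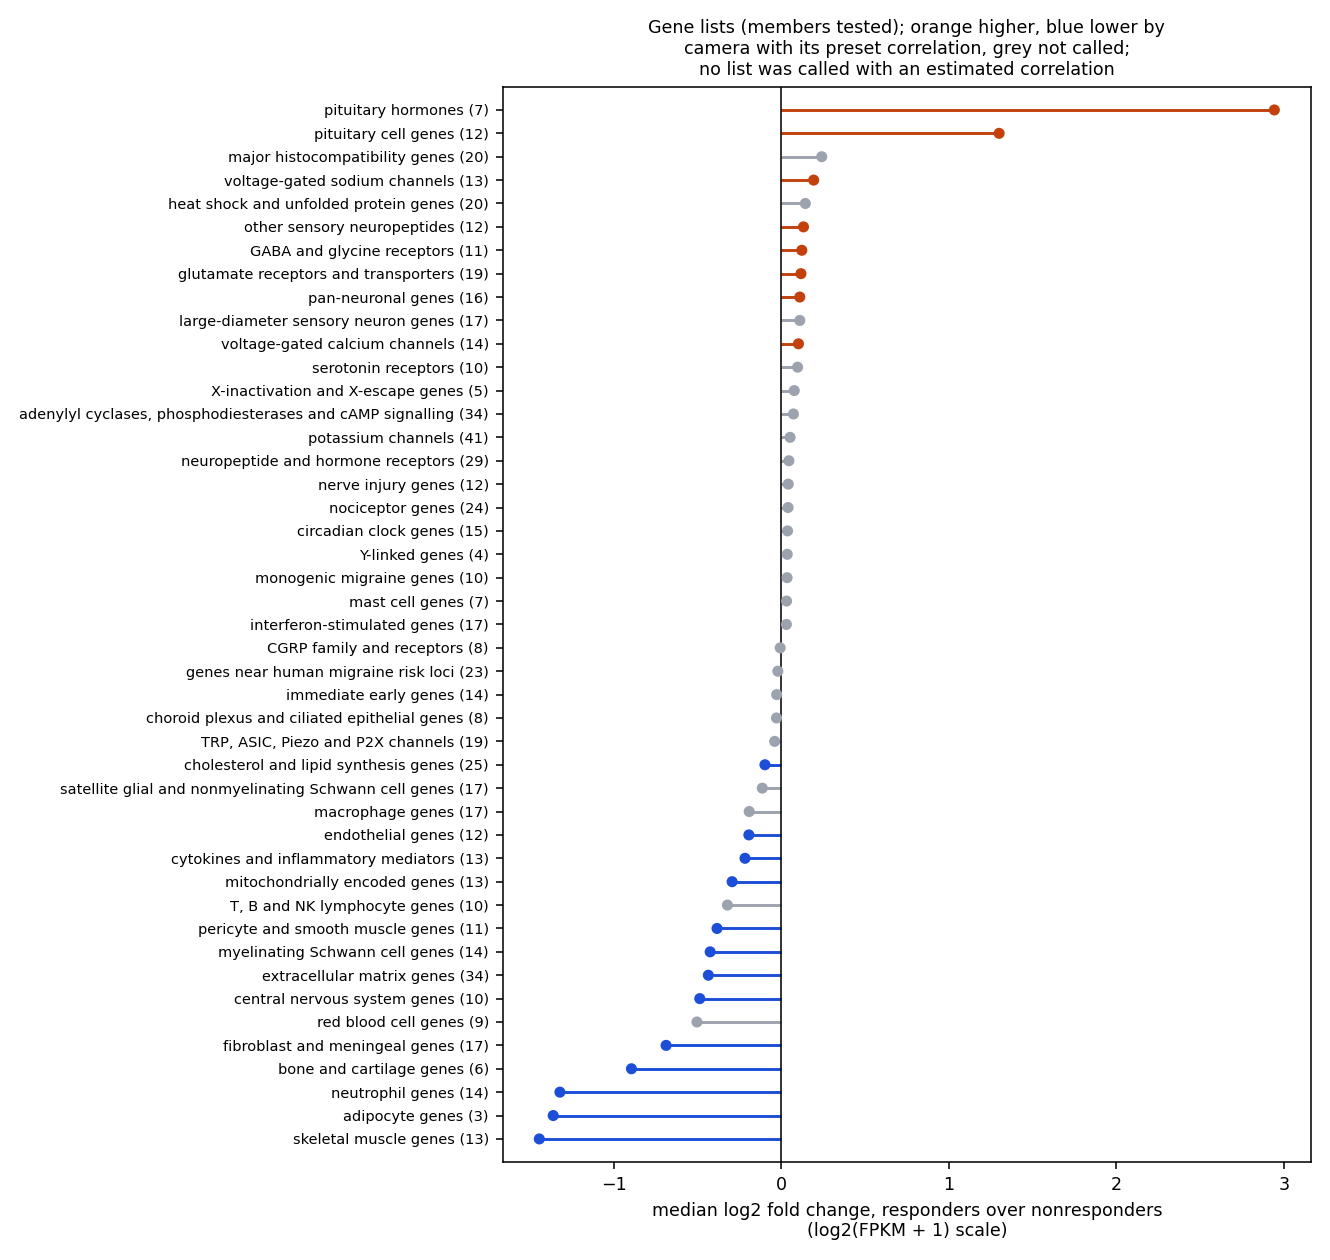
Median log2 fold change of each of the 45 tested lists on the log2(FPKM + 1) scale (horizontal axis), with the number of tested members in brackets and color for the camera call at its preset correlation. The pituitary hormones, at 2.94, and skeletal muscle genes, at -1.45, lay farthest from 0.

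The other 24 lists were not called, with camera adjusted p from 0.07 to 0.869. The nociceptor list had a median of 0.04 (adjusted p = 0.299, and adjusted p = 0.823 with an estimated correlation), yet 3 of its members passed when adjusted over the list alone: the irritant receptor gene Trpa1, at 12.3 ± 2.49 FPKM in responders and 8.18 ± 1.87 in nonresponders, and the itch receptor gene Il31ra, at 4.09 ± 0.715 and 2.82 ± 0.641, were higher, and the cold receptor gene Trpm8, at 2.92 ± 1.45 and 6.04 ± 1.81, was lower (n = 6 per group). Among genes near human migraine risk loci (median -0.02, camera adjusted p = 0.09, and adjusted p = 0.525 with an estimated correlation), 3 passed likewise, all lower: Trpm8, the potassium channel gene Kcnk5, at 3.56 ± 0.767 and 5.39 ± 0.874, and Mrvi1, at 2.14 ± 0.680 and 3.84 ± 0.981. By fry's test for change in either direction, this was the 1 list that passed (adjusted p = 0.0364). The matrix and myelinating Schwann cell lists lay at the threshold of that fry test, each with an adjusted p of 0.05. The list of genes near migraine risk loci was called by camera without responder 6 (adjusted p = 0.0221) and without nonresponder 4 (0.0498), and the nociceptor list without responder 1 (0.000262) and without nonresponder 2 (0.0375). Large-diameter sensory neuron genes had a median of 0.11 and a mean of -0.01, with a camera direction of higher (adjusted p = 0.07, and adjusted p = 0.475 with an estimated correlation). In it, Calb1 stood at 25.6 ± 2.78 and 18.01 ± 3.77 and Ntrk3 at 8.38 ± 3.78 and 4.39 ± 1.07. The median, mean and test also differed in sign for the clock, monogenic migraine and TRP channel lists, with camera adjusted p of 0.671, 0.537 and 0.869. The large-diameter list was called without responder 1 (0.00791), nonresponder 2 (0.0307) or nonresponder 6 (0.0444). The smallest limma adjusted p over all genes among the 7 genes named here was 0.339, for Kcnk5.

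The remaining lists were not called either. Median log2 fold changes were 0.14 for heat shock genes (camera adjusted p = 0.0845), -0.50 for red blood cell genes (0.0852), -0.19 for macrophage genes (0.166) and 0.24 for major histocompatibility genes (0.271). They were 0.10 for serotonin receptors (0.226), 0.07 for adenylyl cyclase and cAMP genes (0.24), 0.05 for potassium channels (0.346), -0.03 for immediate early genes (0.346) and 0.04 for nerve injury genes (0.353). X-inactivation genes had 0.08 (0.529), Y-linked genes 0.04, lymphocyte genes -0.32, interferon-stimulated genes 0.03 and choroid plexus genes -0.03 (each 0.537), mast cell genes 0.03 (0.62) and neuropeptide receptors 0.05 (0.663). Over all 24 lists adjusted p ran from 0.475 to 0.902 with an estimated correlation. Single mice changed some of these outcomes: red blood cell genes were called as lower without responder 2 (0.0231), responder 3 (0.00552), nonresponder 2 (0.00659) or nonresponder 6 (0.0368), and macrophage genes without nonresponder 2 (0.0103). Serotonin receptors (0.00486 and 0.0307) and potassium channels (0.0232 and 0.0322) were called as higher without responder 1 or without nonresponder 2, histocompatibility genes as higher without nonresponder 4 (0.0253) and clock genes as lower without responder 1 (0.0232).

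Within males, responders had more Gm6166 and less Cthrc1, and within females more Gm6166. Gm6166 ranged from 14.4 to 24.2 FPKM in male responders and from 0.68 to 1.33 in male nonresponders, and from 18.2 to 25.1 and from 0.52 to 1.64 in females (n = 3 per group and sex). Cthrc1 ranged from 0.55 to 0.76 and from 3.52 to 5.31 in males, and from 0.75 to 1.75 and from 4.2 to 5.44 in females. By limma, 2 genes were called in males, Gm6166 (log2 fold change 3.36, adjusted p = 0.00122) and Cthrc1 (-1.70, adjusted p = 0.0192), with 963 at an unadjusted p under 0.05. In females 1 was called, Gm6166 (3.59, adjusted p = 0.000641), with 967 at an unadjusted p under 0.05. With mice averaged by the first number of their description, the Gm6166 call was lost within each sex, as it was with the replicate block (adjusted p = 1 and 0.784). Averaging leaves 1 nonresponder value against 2 responder values in males and 2 against 2 in females, so that these losses say little. The log2 fold change of Gm6166 was then 3.44 in males and 3.57 in females (adjusted p = 0.139). Averaging within groups leaves such sizes much the same in any case. Over all alternatives its adjusted p ran from 2.7e-07 to 1 in males and from 0.000171 to 0.784 in females. Cthrc1 had a log2 fold change of -1.38 in females (adjusted p = 0.103), and Ndufs5 1.21 in males (0.319) and 1.53 in females (0.148), while the tests of the difference between the sexes gave adjusted p of 0.836 for Cthrc1 and 0.86 for Ndufs5. The Cthrc1 call in males was lost without responder 1, responder 2, responder 6, nonresponder 2, nonresponder 5 or nonresponder 6, with adjusted p of 0.0531 to 0.0988 within a range of 2.29e-06 to 1 over all alternatives. The count in males was 5 without responder 3 or nonresponder 3, 4 without responder 4, 5 or 6 or nonresponder 1, and 1 without responder 1 or nonresponder 6. In females it was 5 without nonresponder 2, 3 without responder 2, 3 or 5 or nonresponder 4, and 2 without responder 1 or 4 or nonresponder 1, 3 or 6.

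The response differed between the sexes for 0 genes by limma, with 711 at an unadjusted p under 0.05 where chance gives 710, and for 0 genes with trend and robust options. With array weights 508 genes passed, in a fit whose weights were extreme. The smallest adjusted p was 0.0652, for Resp18, a protein of neuroendocrine secretory granules. In males Resp18 stood at 7.51, 10.6 and 12.4 FPKM in responders against 2.44, 2.01 and 2.44 in nonresponders, and in females at 2.24, 3.77 and 2.68 against 5.02, 8.54 and 6.50 (log2 fold change 1.74 in males and -0.97 in females). It passed without responder 1 (adjusted p = 0.0249), without responder 4 (0.0421) and without nonresponder 1 (0.0361), within a range of 0.000893 to 1 over all alternatives. Without 1 mouse the count of genes was 3 (responder 6), 2 (responder 1 or 4, nonresponder 1, 2 or 5) or 1 (responder 3, nonresponder 3 or 4). Camera called 12 of 45 lists for a difference between the sexes, among them the pituitary hormones, with a median of 4.61 in males and 1.27 in females. Each had an adjusted p = 0.835 with an estimated correlation, by which 0 were called (0 at an unadjusted p under 0.05).

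Females differed from males mainly in genes of the sex chromosomes. Xist, the RNA that silences an X chromosome, ranged from 11.1 to 16.02 FPKM in females and from 0 to 0.03 in males. Of the Y-linked genes, Eif2s3y ranged from 15.4 to 22.4 in males and from 0 to 0.05 in females, Uty from 3.3 to 5.61 in males and was listed at 0 in females, Ddx3y from 1.08 to 2.76 in males and from 0 to 0.02 in females, and Kdm5d from 1.16 to 1.7 in males and at 0 to 2 decimals in females. Each mouse thus carried the transcripts of its labelled sex. Fbxo9, which encodes an F-box protein and lies on chromosome 9, stood at 9.44 ± 3.30 in males and 3.71 ± 0.510 in females (SD, n = 6 per sex). By limma 8 genes were called, 2 higher in females (Xist, log2 fold change 3.85, and Gm2223, 0.57) and 6 lower (Eif2s3y, -4.31, Uty, -2.45, Gm29650, -2.09, Ddx3y, -1.40, Kdm5d, -1.27, and Fbxo9, -1.10), with 643 at an unadjusted p under 0.05. Gm2223 shares 1350 bases at 100% with the X-linked gene Eif2s3x, so that its value is uncertain. The Fbxo9 call was lost without responder 2, 3, 4 or 5 or nonresponder 1, 2 or 5 (adjusted p of 0.0707 to 0.103), and that of Gm2223 without responder 2 or 4 or nonresponder 1, 2 or 5 (0.0509 to 0.066).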

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

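The tests of pituitary cell genes against the hormones, of the hormone level between the groups, of the ratios to near-identical partners and of the Schwann cell score minus the satellite glial, endothelial and macrophage scores were chosen only after the result was seen, and the fit without responder 1 and nonresponder 4 was added after the data were examined.

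A single mouse stood far from the other 5 of its group for 13 of 188 gene groups and 8 of 90 list groups. The bound was a gap of more than 0.625 of the group's range, which chance gives in about 1 of 20 groups. Gaps and ranges were taken on the log2(FPKM + 1) scale, while the gene values given here are FPKM. Responder 1 accounted for 5 of the genes. It had 3.88 FPKM of Calcrl against 1.57 to 2 in the other responders (share of the range 0.758), 34.15 of Snap25, a synaptic membrane protein gene, against 5.63 to 9.23 (0.74), 76 of Hmgcs1 against 110.15 to 131.33 (0.678), 45.78 of Fabp5 against 69.12 to 82.99 (0.692) and 125.68 of Npm1 against 61.8 to 79.63 (0.644). Nonresponder 5 had 1.95 of Tshb against 0.33 to 0.77 (0.64), 0.4 of Pou1f1 with the other nonresponders listed at 0 (1) and 15.84 of Hspd1, a mitochondrial chaperone gene, against 18.62 to 20.16 (0.669). Nonresponder 4 had 4.62 of Trpa1 against 7.86 to 9.78 (0.7) and 111.46 of Npm1 against 65.92 to 79.63 (0.641), and nonresponder 2 had 9.9 of Snap25 against 4.95 to 5.73 (0.798). For the pseudogenes, responder 5 had 2.62 of Gm8730 against 17.06 to 42.4 (0.647), and responder 2 had 7.69 of Gm9118 against 0.29 to 0.58 (0.894).

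Among list scores, the mean log2 value of the members, responder 1 stood apart for serotonin receptors, at 1.79 against 2.25 to 2.4 (0.752), nociceptor genes, at 3.3 against 3.86 to 4.15 (0.653), and clock genes, at 3.05 against 2.12 to 2.44 (0.654). Nonresponder 4 stood apart for GABA and glycine receptors, at 3.15 against 3.57 to 3.77 (0.688), and satellite glial genes, at 4.48 against 4.69 to 4.78 (0.69). The others were nonresponder 1 for adenylyl cyclase and cAMP genes, at 2.87 against 3.07 to 3.17 (0.658), nonresponder 3 for choroid plexus and ciliated epithelial genes, at 2.47 against 0.77 to 1.27 (0.706), and responder 5 for interferon-stimulated genes, at 3.26 against 2.06 to 2.44 (0.687).

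The difference between responders and nonresponders itself differed between the sexes for 12 lists by camera, each with an adjusted p = 0.835 with an estimated correlation. Pituitary cell genes had a median log2 fold change of 2.22 in males and 0.39 in females (adjusted p = 0.00398), neutrophil genes -2.36 and -0.15 (0.00398), lymphocyte genes -0.96 and 0.28 (0.00398), pituitary hormones 4.61 and 1.27 (0.0071), skeletal muscle genes -0.10 and -2.33 (0.0071) and fibroblast genes -0.17 and -0.92 (0.0071). Choroid plexus genes had 0.30 and -0.56 (0.0071), clock genes 0.11 and -0.16 (0.0071), nociceptor genes -0.13 and 0.26 (0.00823), interferon-stimulated genes -0.13 and 0.24 (0.041), pericyte genes -0.06 and -0.47 (0.0438) and pan-neuronal genes -0.10 and 0.30 (0.0438). Each of these calls was lost without some single mouse. Without responder 1 this held for the pituitary cell genes (0.266), hormones (0.128), clock (0.313), nociceptor (0.781), pan-neuronal (0.476) and pericyte lists (0.313), and without nonresponder 4 for the neutrophil (0.203), lymphocyte (0.133) and interferon lists (0.387). Without nonresponder 2 it held for the fibroblast (0.352), nociceptor (0.264), pan-neuronal (0.523), pericyte (0.406) and muscle lists (0.0706), and without nonresponder 3 for the fibroblast (0.137), choroid plexus (0.0832), pan-neuronal (0.193), pericyte (0.338) and muscle lists (0.136). Others were responder 2 (interferon 0.118, muscle 0.0943), responder 3 (neutrophil 0.0628), responder 4 (pan-neuronal 0.0726, pericyte 0.0758), responder 5 (interferon 0.889, nociceptor 0.0652, pan-neuronal 0.114, pericyte 0.0734), responder 6 (fibroblast 0.0895, interferon 0.108), nonresponder 1 (interferon 0.102) and nonresponder 5 (pan-neuronal 0.166, pericyte 0.182, muscle 0.166). Over all alternatives adjusted p reached 0.889 among these lists, and without both responder 1 and nonresponder 4, 12 lists were called, 6 of them among those above.

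Pituitary hormone transcripts were highest in responders 1, 2 and 3 for Gh, and Gh and Prl were listed above 0 in all 12 mice. Pituitary tissue taken along with the ganglion may be a source of them: over the 12 mice the genes of pituitary cells that are not hormones followed the mean hormone level with a median Spearman rho of 0.859, from 0.028 to 0.965, and the scores correlated with r = 0.957 and rho = 0.972 (permutation p of 1e-05 for each, the smallest these permutations can give). Without responders 1 and 2, the mice farthest from the median, r was 0.876. The higher hormone level in responders (exact permutation p = 0.026, 2-sided, 0.211 after adjustment over the lists) restates the observation and tests no cause, so that a difference that goes with the response stays open and untested. Whether the ganglia of the groups were dissected by the same hands or on the same days was not tested.

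Gm6166 and Ndufs5, 2 of the 3 called genes, share a stretch of near-identical transcript with another gene, Fabp5 and BC002163; the other 4 matches of Gm6166 were listed at no more than 0.22 FPKM in any mouse, and no ratio to them was taken. The test asked whether a fixed share of the partner's reads had been counted on the gene, and set as its bound that the ratios of the 12 mice separate for every gene; after 2 of 5 genes met it, the genes were weighed in 2 parts. Over all 5 genes the bound was not met. Ratios were of FPKM + 1, which shrinks those of genes near 1 FPKM. For Gm6166 the log2 ratio to Fabp5 was -1.70 ± 0.14 in responders and -5.55 ± 0.17 in nonresponders. For Ndufs5 that to BC002163 was 1.37 ± 0.37 and 0.09 ± 0.24 (n = 6 per group, exact permutation p = 0.00216 each, 2-sided, the smallest possible). These 2 were picked as called genes, but a fixed share needs the partner to change alike. Fabp5 was not higher in responders, and BC002163 ranged from 12.03 to 19.68 FPKM in responders and from 11.55 to 18.27 in nonresponders. With a median absolute difference of 2.57, this argues against a fixed share for these 2 genes only. For Gm8730 (to Rplp0), Gm9118 and Gm6477 (to Npm1), not called, the median was 2.05 (exact permutation p of 0.0108, 0.0108 and 0.00649). These were chosen after their values were seen and mice overlapped, so that a fixed share stays undecided. Inherited differences between the families may contribute, and the 50 genes with the smallest p held 5 pairs within 2 Mb against a median of 3 in 10000 random sets (permutation p = 0.263, 1-sided), which decides nothing. An allele of Fabp5 or BC002163 nearer in sequence to the other gene stays open and untested, with Fabp5 itself at 68.9 ± 12.5 FPKM in responders and 90.1 ± 19.9 in nonresponders (limma adjusted p = 0.64).

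Schwann cell, fibroblast and matrix lists were called as lower in responders by camera, but each had an adjusted p = 0.475 with an estimated correlation and an exact permutation p of 0.211 after adjustment, and other splits of the mice called as many lists, so that chance stays open. Responder 1 and nonresponder 4, which stood apart, do not account for the lower values, since without both the medians of the 3 lists kept at least 90.7% of their size. That fit does not cover other mice: without nonresponder 3 the fibroblast median was -0.46 in place of -0.69, still called by camera (adjusted p = 1.75e-05). A lower share of every non-neuronal cell type stays open: the Schwann cell score was lower relative to the satellite glial score (exact permutation p = 0.0368, 2-sided) but not past the test relative to the endothelial (0.355) and macrophage scores (0.407), and 11 of 12 endothelial and all 11 pericyte genes were lower too. A varying amount of nerve root and connective tissue in the dissection may be a cause: genes of fat (median -1.36), bone (-0.90), skeletal muscle (-1.45) and pericytes (-0.38) were lower as well, while within groups the Schwann cell and fibroblast scores had r = 0.151 (exact permutation p = 0.589) and rho = 0.049 (0.889), and r = -0.033 without the 2 farthest mice, which leaves it open. All 13 mitochondrially encoded genes were lower too (median -0.29), and RNA quality, a difference in the ganglion that goes with the response, or one with the numbers that open the sample descriptions, remain open and untested.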

How the results depend on the processing

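The fits without responder 1 and nonresponder 4 and with tissue scores as covariates were chosen only after the data were seen. Of 2298 gene values computed under an alternative, 2209 kept their direction and side of the threshold, 51 lost and 12 gained a call, 0 called values changed sign and 26 uncalled values did. For lists, direction was that of camera and not of the median. Of 1026 list values, 852 kept both, 87 lost and 37 gained a call, 3 called lists changed direction and 47 uncalled ones did. The 3 arose under tissue scores as covariates, with medians of -0.109 for pituitary cell genes, 0.015 for neutrophil genes and 0.14 for skeletal muscle genes. This follows from construction for neutrophil and muscle genes, whose own scores were covariates, and for pituitary cell genes from their relation to the hormone score, another covariate. The median of calcium channels also changed sign in that fit, to -0.015 (camera adjusted p = 0.59), without a change of direction. Medians of some uncalled lists crossed 0 likewise, such as nociceptor genes, down to -0.018.

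The counts of called genes moved as follows, and the cause was not tested unless given. Over all mice the count of 3 became 1 with the replicate block, 1 with mice averaged by the number that opens their description and 1 with tissue scores as covariates. In males the count of 2 became 5787 with array weights, 4 with a pseudocount of 0.1, 0 with the replicate block, 0 with averaged mice, 1 without responder 1 and nonresponder 4, and 4 with only the 6 males. In females the count of 1 became 11 with array weights, 5 with no filter on low values, 2 with a mean of at least 5 FPKM, 0 with the replicate block, 0 with averaged mice, 3 without responder 1 and nonresponder 4, and 11 with only the 6 females. Averaging leaves 7 values, with 1 male nonresponder value against 2 of male responders and 2 against 2 in females, so that the counts of 0 with averaged mice follow largely from the design. At these counts of 0 limma still gave, at an unadjusted p under 0.05, 440 and 694 genes in males and 818 and 1010 in females. For the interaction the count of 0 became 508 with array weights and 1 with a mean of at least 5 FPKM. The weights of that fit did not converge and reached 21.4 in nonresponder 5 and 7.35 in responder 2 against 0.142 in responder 1, so that 508 and 5787 rest on few mice. Females against males gave 3 in place of 8 with a mean of at least 5 FPKM, where fewer genes were tested, and 5 with the replicate block. Camera called 12 lists in place of 21 with a mean of at least 5 FPKM.

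With each mouse left out in turn, the count was 2 to 6 over all mice, 1 to 5 in males, 1 to 5 in females, 0 to 3 for the interaction, 6 to 9 for females against males and 12 to 25 for the lists. The replicate numbers do not pair the mice: deviations of mice with the same number correlated with -0.019, -0.18, 0.032, -0.273, 0.013 and 0.133, and 0 of 6 pairs correlated best with their own number. With the block, 20 lists were called. Within 1 group and sex, mice that shared the number opening their description had a mean r of 0.93 over 6 pairs. Those that did not had 0.945 over 6 pairs. Responder 1 and nonresponder 4, whose mean r with the other mice was lowest (0.899 and 0.887), fell in more of the pairs that shared a number. This comparison therefore cannot decide whether the number matters. Low genes such as Adcyap1r1 and Vipr2 lay below the filter on FPKM, and whether depth limited them was not tested.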

Other observations

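All genes in the next paragraphs were chosen after their values were seen. Rcan3, which encodes a regulator of calcineurin, stood at 7.66 ± 1.603 FPKM in responders and 3.11 ± 1.21 in nonresponders (SD, n = 6 per group), higher in each responder than in every nonresponder. It did not pass limma over all mice (adjusted p = 0.0919) and passed without responder 3 (0.0365) or without nonresponder 5 (0.0385), within 0.0365 to 0.481 over all alternatives. Itm2a, a membrane protein gene, stood at 44.4 ± 7.35 and 81.4 ± 14.1, lower in each responder, with an adjusted p of 0.125, and passed without responder 6 (0.0159, within 0.0159 to 0.818). Hspd1 stood at 10.6 ± 7.05 and 18.9 ± 1.61, with responder 6 at 24.63, and passed without that mouse (0.00629, within 0.00629 to 0.912).

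Some abundant genes had a wide gap between mice, with no difference between the groups past the test. Of 5069 genes with a median of at least 10 FPKM, 28 had a gap of at least 4-fold with at least 2 mice on each side, and 24 of these were protein coding. Not all of these took 1 of 2 levels: Gh, from 18.09 to 63428.56 FPKM, and Mb, from 1.69 to 186.57, had wide ranges. By limma 0 of the 28 differed with the response, with 6 at an unadjusted p under 0.05, beside 1051 of all 14203 genes tested. Actb, the cytoskeletal actin gene, lay between 9.71 and 18.43 FPKM in 7 mice and between 169.71 and 355.66 in 5. Casc3, a gene of the exon junction complex, was listed at 0.04 and 0.03 in responders 1 and 2 and between 13.82 and 17.58 in the others. The mitochondrial gene mt-Atp6 stood at 2757.54 and 3075.41 in nonresponders 1 and 4 and between 381 and 587 in the others.

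Other splits of the mice tested whether chance can be excluded. The shares below were not adjusted over the comparisons. Over all mice, responders against nonresponders gave a count that was rare under chance but not beyond it, if the 12 mice are independent. Of 100 sex-balanced splits, the real one included, 2 gave as many calls as the real 3, and the highest of the others was 3. Whether mice that share the number opening their description are independent is not settled. With mice averaged by it the count was 1, but on 7 values. The log2 fold changes of Ndufs5 (1.39) and Cthrc1 (-1.55) were as large, which averaging within groups gives whether or not the number matters. Mice of 1 group and sex had a mean r of 0.93 with the same number and 0.945 with another. Responder 1 and nonresponder 4, which stood apart, fell in more of the pairs with the same number, so that this r cannot decide it. The sex-balanced splits that keep mice of 1 number together, counted only after the result was seen, are 4 (real 3, highest other 1), too few for a share under 0.05. For females against males chance can be excluded, since only the real split of 100, 1 in all, gave as many as the real 8, with 2 as the highest of the others. For the gene lists chance cannot be excluded, since 6 of 100 splits, the real one included, called at least as many as the real 21. The highest of the others called 24, and their median was 11. Of the other splits, 0 called no list at all. For the interaction the splits say nothing about chance, since a real count of 0 is matched by 100 of 100 splits whatever the data; the highest of the others was 8 and 73 of them gave 0, and what that highest split holds was not tested. Within males (real 2, highest other 2) and within females (real 1, highest other 2) the 10 splits are too few for a share under 0.05.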
